A study of Mus musculus with 20 samples.

How the data were processed

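Messenger RNA from 20 mouse libraries had been sequenced by the authors as stranded paired-end reads: 4 gates of resident macrophages, 4 libraries of infiltrating cells, 6 of mdx muscle and 6 of injured muscle. The values are FPKM (fragments scaled by transcript length and by the number of mapped fragments) as deposited by the authors, in 4 tables, one per experiment. Per the labels, bcl2fastq, Bowtie, STAR, Cufflinks and the mm10 build were used, with no versions, roles or order given. Column sums of FPKM differ between libraries. In 3 tables the lowest value is 0.01 FPKM, a floor written in place of smaller values, and the infiltrating table has true zeros.

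Samples were grouped by the labels. After removal of 50 entries whose names a spreadsheet had turned into dates and of 2 overwritten entries, 24338 genes were used for resident macrophages, 16836 for infiltrating cells, 24340 for mdx muscle and 24313 for injured muscle. A text mark in place of a value was read as missing for 3 genes in mdx muscle and 10 in injured muscle, and these genes were not tested, except where a setting left out every library without a value. Myh4 and Atp2a1 in mdx muscle are among them. No mitochondrially encoded transcripts could be assessed, since their share of FPKM was 0.0% in every library.

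Alignments per library are listed for infiltrating cells only, from 25953400 to 34655400. For the other tables relative depth was estimated from values under 0.2 FPKM, where the smallest values are whole multiples of 1 fragment and the most frequent ratio between libraries gives their ratio of depths. In infiltrating cells the estimates were 0.924, 0.756 and 0.92 of day 2, and the alignments gave 0.922, 0.749 and 0.926. The absolute depth of the other tables is unknown, so no counting interval is given.

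Values were transformed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the libraries of a table were tested. Whole-muscle comparisons used limma-trend (limma 3.58.1 in R 4.3.3, eBayes with trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. For mdx muscle the model had diet, with 3 libraries per diet. For injured muscle it had diet and hours after injury, and the contrast of times came from the same fit. A model with 4 cell means tested whether the effect of the diet differed between times, where each lone 12 h library is assumed to vary like those of 18 h. Tables were tested separately, and no test was made between tables.

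Before the data were examined, 35 gene lists, the models, the rule for named genes and the alternatives were fixed. Lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which tests a list by itself, were alternatives. Counts adjusted over the list alone repeat the adjustment among a list's own members. Some genes stand in more than 1 list.

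Named genes were the 12 largest changes each way past the threshold with every PLX library on one side of every control (within the time for injured muscle), up to 4 members of each list past the threshold, and 12 single genes fixed with the rule. Cd163, Lyve1 and Timd4 among these were below the filter in mdx muscle, as were Myh7 and Timd4 in injured muscle. For the contrast of times the rule took 8 genes each way and for the difference between times 4. Predicted genes, immunoglobulin and T cell receptor segments, mitochondrially encoded and histone genes and pseudogenes were not named. Members of a list with large changes served as examples. The text gives part of the list members past the threshold, and the others are not reported here.

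Sorted cells had 1 library per gate or time except on day 4, so they were described by fixed size rules of 2-fold on FPKM + 1 and not tested. The 10 genes each way with the largest gaps and a mean of at least 5 FPKM were named, with class II genes and Cx3cr1 kept apart because the gates select on them. The median of each list was placed among 10000 random lists matched on mean expression in 20 bins, and percentiles come from these. Random lists draw genes independently, while members of a list can vary together, so the percentiles can overstate the evidence. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

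The tests were tested on simulated data with known changes. In the mdx design 86 of 100 genes with a log2 change of 1 and 100 of 100 with a change of 2 were recovered, with 7 false calls among 193. In the injury design 82 and 99 of 100 were recovered, with 9 false calls among 190. In both designs the noise was drawn independently for each gene from the fitted spread. No simulated library stood apart and no genes varied together, so these shares need not hold for the real libraries. For the size rules, log2 changes of 1.5 and 3 were planted with noise of SD 0.1, and 100 of 100 changed genes were recovered with 0 false calls. Both sizes lie well beyond the 2-fold cut for so little noise, so this outcome was built in. It does not show how often the rules call falsely between single libraries, whose noise is unknown.

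The alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, rescaling to TPM or by median-of-ratios, no variance trend, title prefix as a block, reporter genotype as a covariate, the 18 h libraries alone, each library left out in turn, a 4-fold size rule and limma-trend on the sorted cells. Leaving out genes of small RNAs was added after seeing the data. For chance, each of the 10 splits of 6 libraries into 3 and 3 was fitted. Coordinates count from 1 on mm10.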

Results

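RNA was sequenced from 20 mouse skeletal muscle libraries, and the values came in 4 separate tables of gene expression. The first table held 4 gates of resident macrophages sorted from uninjured muscle of male mice with green fluorescent protein (GFP) at the Cx3cr1 locus, with 1 library per gate. All 4 gates were F4/80 and MERTK positive, and they differed in surface class II major histocompatibility complex (MHCII) and in GFP. The second table held GFP-labelled myeloid cells that had reached the injured tibialis anterior of unlabelled female mice surgically joined to GFP mice (parabiosis), with 1 library at day 2, 2 at day 4 and 1 at day 6 after injury. The third table held whole tibialis anterior of 8-month-old female mdx mice, which lack dystrophin, after 6 months of control diet (3 libraries) or of a diet with PLX73086 (3 libraries). PLX73086 is an inhibitor of CSF1R, the receptor for the macrophage growth factor CSF1, and was given at 200 mg per kg of food. The fourth table held whole injured tibialis anterior of male mice that had received the control or the PLX diet for 3 weeks and regular food for 3 days before injury. It had 2 libraries per diet at 18 h and 1 per diet at 12 h after injury.

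Numbers of alignments were listed for the infiltrating cells, at 34655400 on day 2, 31958500 and 25953400 on day 4 and 32073800 on day 6. For the other tables only relative depths were estimated, from the spacing of the smallest values. They were 0.903, 0.821 and 0.641 of the MHCII- GFP- library for the MHCII+ GFP-, MHCII+ GFP+ and MHCII- GFP+ gates. The mdx libraries lay between 0.802 and 1.08 of control replicate 3, and the injured libraries between 0.656 and 1.05 of PLX 18 h replicate 1. Counts per gene are not given in the sources used here, so no counting interval is printed. The levels of Xist and Ddx3y matched the sex in the labels of all 20 libraries.

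In dystrophic muscle, the comparison asked what long CSF1R inhibition did to the tissue. By camera with its preset correlation, resident macrophage and fast fibre transcripts were lower under the PLX diet and those of oxidative metabolism and of slow fibres higher, and none of these lists was called with an estimated correlation (lowest adjusted p 0.673). F13a1, which encodes the A subunit of coagulation factor XIII and is made by resident macrophages, fell from 1.92 ± 0.218 to 0.284 ± 0.128 FPKM (SD, n = 3 each; log2 change -1.19, adjusted p = 0.0352). Mss51, a skeletal muscle gene linked to mitochondrial metabolism, fell from 28.8 ± 0.656 to 8.30 ± 1.84 FPKM (log2 change -1.70, adjusted p = 0.0235). Serpinb1a, an inhibitor of neutrophil proteases, rose from 8.54 ± 2.07 to 35.4 ± 3.41 FPKM (log2 change 1.95, adjusted p = 0.0235).

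Across 10197 tested genes, limma-trend called 13 genes higher and 3 lower in PLX-fed mdx muscle at an adjusted p under 0.05. Serpinb1a lies on chromosome 13 from 32842092 to 32851185, F13a1 on chromosome 13 from 36867178 to 37050244 and Mss51 on chromosome 14 from 20482864 to 20496901 of the mm10 build. Besides Serpinb1a, the higher genes were Prr32 (log2 change 1.38), the matrix protease Mmp3 (1.34), the microtubule protein Map1a (1.32), the ubiquitin hydrolase Uchl1 (1.25), the regulator of lipid synthesis Mid1ip1 (1.21), S100a13 (1.15), Osbpl3 (0.96), Fndc1 (0.91), Aig1 (0.91), the tumour necrosis factor receptor Tnfrsf1a (0.88) and the interleukin signalling kinase Irak2 (0.81). The remaining one was Slc38a2, an amino acid transporter (0.68), which was named after its values were seen. Prima1, the membrane anchor of acetylcholinesterase, was the third lower gene (-1.47). The smallest adjusted p was 0.0235, and 1648 genes had an unadjusted p under 0.05 where 510 were expected by chance.

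Among 19 resident macrophage genes, 10 were measured above the filter and 9 of these were lower under PLX. The list fell as a whole (median log2 change -0.86, adjusted p = 0.000153 by camera), and its adjusted p was 0.673 with an estimated correlation. F13a1 passed over all genes, and 6 members were lower when adjusted over the list alone, among them Pf4 (-2.33), Folr2 (-1.83), Clec10a (-1.25) and the mannose receptor Mrc1 (-1.03). One member, the efferocytosis ligand Gas6, was higher over the list alone (0.36). The pan-macrophage list fell (14 of 15 members negative, median -0.84, adjusted p = 0.00359; adjusted p = 0.771 with an estimated correlation), and no member passed over all genes or over the list alone. Csf1r itself averaged 1.50 ± 0.788 FPKM under PLX and 7.69 ± 7.54 in controls (-1.49, adjusted p = 0.272), and Adgre1, which encodes F4/80, had a log2 change of -1.06 (adjusted p = 0.386). Control replicate 2 stood apart from the other mdx libraries, with Csf1r at 16.3 FPKM against 4.38 and 2.37 in the other controls. Without control replicate 2 the pan-macrophage median was -0.12 (adjusted p = 0.603), and without PLX replicate 1 it was -0.65 (adjusted p = 0.0517), while it reached -1.495 without control replicate 1. The resident macrophage median was -0.64 without control replicate 2 (adjusted p = 0.00888), and its call ended when only genes of mean FPKM of at least 5 were tested (-0.46, adjusted p = 0.19). Class II genes fell too (6 of 6 negative, median -0.999, adjusted p = 0.00223; adjusted p = 0.673 with an estimated correlation), led by H2-Eb1 (-1.13) and H2-Aa (-1.06), with a median of -0.60 without control replicate 2. No class II gene passed over all genes, and 1 passed over the list alone.

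Genes of mitochondrial metabolism and of slow fibres were higher and those of fast fibres lower. All 31 measured genes of oxidative phosphorylation had positive changes (median 0.27, adjusted p = 1.9e-09), led by the cytochrome oxidase subunits Cox5b (0.48), Cox7a1 (0.40) and Cox8b (0.39), and none passed singly. Fatty acid oxidation genes rose (21 of 22 positive, median 0.33, adjusted p = 7.3e-05), with the fatty acid carriers Fabp3 (0.97) and Cd36 (0.73) largest. The citric acid cycle list rose (15 of 16 positive, median 0.17, adjusted p = 0.00839). The adjusted p was 0.673 for oxidative phosphorylation, 0.743 for fatty acid oxidation and 0.771 for the citric acid cycle with an estimated correlation. Glycolysis genes were not called (11 of 17 negative, median -0.05, adjusted p = 0.0628). Slow fibre genes rose (9 of 9 positive, median 0.78, adjusted p = 0.00839), with the slow troponins Tnni1 (1.30) and Tnnt1 (1.20) largest, and fast fibre genes fell (9 of 10 negative, median -0.18, adjusted p = 0.000598), with Actn3 (-0.76), parvalbumin Pvalb (-0.72) and Mybpc2 (-0.60) among 4 that were lower over the list alone. Both fibre lists had an adjusted p of 0.673 with an estimated correlation. The exception among fast fibre genes was Myh1, the type IIX myosin, at 2510 ± 758 FPKM under PLX and 1201 ± 305 in controls (1.05, adjusted p = 0.149, higher over the list alone). Myh2 had a log2 change of 0.66 (adjusted p = 0.475), Myh7 of 0.02 (adjusted p = 0.992) and Dmd of -0.02 (adjusted p = 0.958), and Myh4 lacked a value in 2 control libraries. The slow fibre call ended without control replicate 3 (0.67, adjusted p = 0.0678) or control replicate 1 (0.47, adjusted p = 0.0652), and the citric acid cycle call without control replicate 2 (0.08, adjusted p = 0.29) or PLX replicate 1 (0.09, adjusted p = 0.264). The oxidative phosphorylation median was 0.18 without control replicate 2, and that of fatty acid oxidation was 0.21 without control replicate 2 or without PLX replicate 1.

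Stress, progenitor and matrix genes were also higher in PLX-fed mdx muscle. The immediate early and heat shock list rose (11 of 12 positive, median 0.99, adjusted p = 3.6e-06), with 8 members higher over the list alone, led by the metallothioneins Mt2 (2.83) and Mt1 (2.18) and the transcription factors Egr1 (1.78) and Atf3 (1.73). Fibro-adipogenic progenitor genes rose (12 of 12 positive, median 0.77, adjusted p = 1.0e-05), with 6 members higher over the list alone, among them Pi16 (1.30) and Mfap5 (1.27). The reporter was carried by 2 controls and 1 PLX library, the control without it (control replicate 3) had a list mean of 4.514 against 4.511 in PLX replicate 3, and with reporter genotype as a covariate the median was 0.60. Mast cell proteases rose (4 of 4 positive, median 0.63, adjusted p = 0.00359), and all 4, led by Mcpt4 (0.81), were higher over the list alone. Each of these 3 lists had an adjusted p of 0.673 with an estimated correlation, and no member of them passed over all genes. The extracellular matrix list rose (14 of 22 positive, median 0.31, adjusted p = 0.00529), with Timp1 (1.47) and fibronectin Fn1 (0.93) higher over the list alone, while Col1a1 had a change of -0.22 (adjusted p = 0.754). The list of regenerating muscle rose (10 of 11 positive, median 0.53, adjusted p = 0.0426), with Myh8 (1.11) and Ncam1 (0.79) higher over the list alone. Both had an adjusted p of 0.771 with an estimated correlation. The progenitor gene Pdgfra had a log2 change of 0.43 (adjusted p = 0.579). Other stromal lists were not called by camera. Their medians were 0.25 for endothelium (adjusted p = 0.149), 0.11 for smooth muscle and pericytes (0.28) and 0.11 for tendon (0.694). They were -0.01 for Schwann cells (0.958) and 0.62 for adipocytes (0.0965). The matrix call ended without control replicate 1 (0.19, adjusted p = 0.075) or PLX replicate 2 (0.11, adjusted p = 0.368), and the median was 0.47 without control replicate 2 and 0.48 without PLX replicate 3. The regeneration call ended without control replicate 1 (0.22), control replicate 3 (0.23), PLX replicate 2 (0.41) or PLX replicate 3 (0.56), and the median reached 1.13 without control replicate 2.

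**Figure D1:**
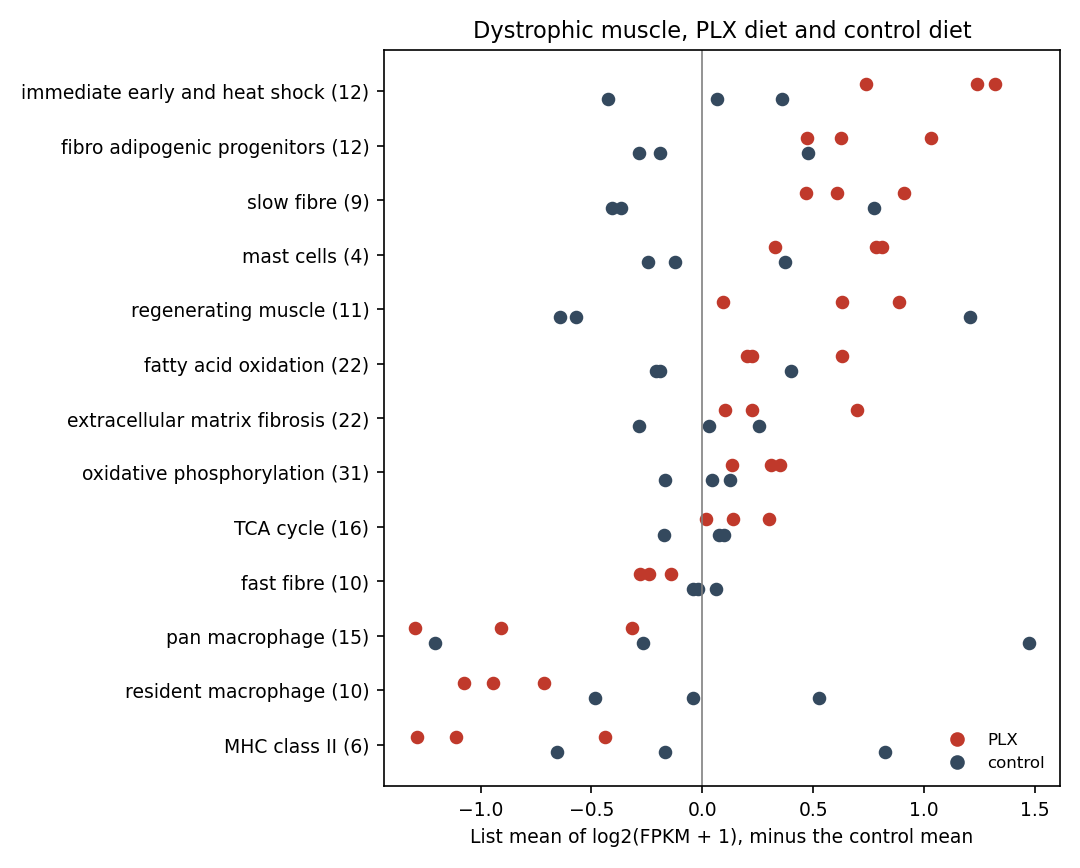
List levels in dystrophic muscle. Each point is 1 library, the x axis is the mean log2(FPKM + 1) of a list's tested genes minus the mean of the 3 control libraries, red marks the PLX diet and dark blue the control diet, and the number of genes is in parentheses; the PLX libraries lie above every control for oxidative phosphorylation and below every control for the resident macrophage and fast fibre lists, while 1 control stands far to the right for the pan-macrophage list.

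Of 30 lists tested in mdx muscle, 9 were higher and 4 lower by camera with its preset correlation, none with an estimated correlation (lowest adjusted p 0.673) and none by the directional fry test, while fry in either direction called 3. The remaining 17 lists had adjusted p values from 0.0628 to 0.958. The gene calls depended on single libraries. No gene passed without control replicate 1, control replicate 2, PLX replicate 2 or PLX replicate 3, where 1250, 1505, 1175 and 1100 genes had an unadjusted p under 0.05, while 5 passed without PLX replicate 1 and 120 without control replicate 3. With no filter on low values 0 genes passed (2139 had an unadjusted p under 0.05).

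In injured muscle, the comparison asked how prior CSF1R inhibition, ended 3 days before the injury, changed the first hours of the response. By camera with its preset correlation, interferon-response and monocyte transcripts were higher after the PLX diet (median log2 changes 2.01 and 0.98) and those of fast fibres, glycolysis and mitochondria lower, and none of these lists was called with an estimated correlation (lowest adjusted p 0.114). Ly6c2, a surface marker of inflammatory monocytes, averaged 125 ± 43.8 FPKM after PLX and 17.9 ± 6.93 in controls (SD, n = 3 each over both times; log2 change 2.73, adjusted p = 0.0165). Irf7, a transcription factor of the interferon response, averaged 96.9 ± 48.5 against 14.0 ± 3.29 FPKM (2.56, adjusted p = 0.0188). Actc1, the cardiac actin that regenerating muscle also makes, averaged 55.3 ± 27.5 against 437 ± 304 FPKM (-2.80, adjusted p = 0.0271).

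With time after injury as a term, limma-trend called 628 genes higher and 721 lower among 11578 tested, and 3563 genes had an unadjusted p under 0.05 where 579 were expected by chance. Ly6c2 lies on chromosome 15 from 75108161 to 75111949, Irf7 on chromosome 7 from 141263183 to 141266424 and Actc1 on chromosome 2 from 114047289 to 114052811. The other large increases were Plac8 (log2 change 2.64), Ifit3 (2.51), Slfn4 (2.48), Ifit1 (2.32), Ms4a4c (2.32), the Fc receptor Fcgr4 (2.30), the chemokine Cxcl13 (2.27), the DNA sensor family member Pyhin1 (2.21) and the antiviral GTPase Mx1 (2.18). Pyhin1 had the smallest adjusted p, 0.00796, shared with the autonomic transcription factor Phox2a, which fell (-2.54, from 14.0 ± 2.30 to 1.58 ± 0.285 FPKM). The small nucleolar RNA Snora7a averaged 11.9 ± 6.69 FPKM after PLX and was at the floor of 0.01 FPKM in all 3 controls, so no size of change is given. The other large decreases were the smoothelin-like protein Smtnl2 (-2.62), Nmrk2 of NAD synthesis (-2.09), Mybph (-2.06), the titin cap Tcap (-2.02), Ppp1r27 (-1.99), the stress cytokine Gdf15 (-1.92), spermine oxidase Smox (-1.89), the Z-disc protein Ldb3 (-1.88), AMP deaminase Ampd1 (-1.87) and Rgcc (-1.84).

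Interferon, monocyte and macrophage lists rose after the PLX diet. Dendritic cell genes (median 0.19, mean -0.19, adjusted p = 0.997, with Cd24a at -1.59 and Cd209a at -1.20 lower over all genes), class II genes (median 0.10, adjusted p = 0.71, with -0.99 at 12 h and 0.69, adjusted p = 0.000784, in the 18 h libraries alone) and mast cell genes (median 0.12, adjusted p = 0.574) were not called. Of 12 type I interferon genes 11 passed over all genes (median 2.01, adjusted p = 1.8e-09), and the list's adjusted p was 0.444 with an estimated correlation. The interferon median was 0.85 in the 12 h libraries, with 1 library per diet. In the same libraries the medians were 1.17 for monocyte, 0.37 for pan-macrophage and 0.57 for resident macrophage genes. They were 0.34 for complement and lysosome genes and 0.31 for repair macrophage genes. Of 12 monocyte genes 8 passed over all genes and 12 over the list alone (median 0.98, adjusted p = 3.3e-08), with Hp (1.12) beside Ly6c2, Plac8 and Ms4a4c. Of 16 pan-macrophage genes 6 passed over all genes and 13 over the list alone (median 0.88, adjusted p = 6.7e-08), including the Fc receptor Fcgr1 (1.42), cathepsin Ctss (1.10) and Itgam (1.09). With an estimated correlation the adjusted p was 0.349 for monocytes and 0.444 for pan-macrophage genes. Csf1r rose from 31.5 ± 1.69 to 54.2 ± 12.1 FPKM (0.74, adjusted p = 0.0337) and Adgre1 from 18.3 ± 4.66 to 37.3 ± 9.45 FPKM (0.99, adjusted p = 0.0227). Resident macrophage genes rose (12 of 15 positive, median 0.80, mean 0.54, adjusted p = 0.000908), with 9 members higher and 1 lower over the list alone. Past the threshold over all genes were 5, among them F13a1 (1.21), the selenoprotein Sepp1 (1.04), Pf4 (0.96) and Mrc1 (0.91). Cd163 (0.96, adjusted p = 0.161) and Lyve1 (0.94, adjusted p = 0.0932) did not pass. Complement and lysosome genes rose (14 of 15 positive, median 0.67, adjusted p = 4.4e-06), with Cfb (1.09) and C3 (0.99), as did repair macrophage genes (12 of 14 positive, median 0.54, adjusted p = 0.000349), with arginase Arg1 (1.50) and Apoe (0.94). These 3 lists had an adjusted p of 0.491, 0.461 and 0.349 with an estimated correlation.

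Cell cycle, neutrophil, progenitor and matrix transcripts were higher as well. Cell cycle genes rose (11 of 11 positive, median 1.14, adjusted p = 5.0e-05), with Rrm2 (1.41) and Ccna2 (1.27) past the threshold over all genes and 7 members over the list alone. Their median was 0.34 at 12 h with 1 library per diet. Neutrophil genes rose (7 of 8 positive, median 0.55, adjusted p = 0.00724), with the protease Mmp8 (1.29) and S100a9 (0.91), as did inflammatory cytokines (11 of 14 positive, median 0.33, adjusted p = 0.0228), with the chemokine Cxcl3 (0.92) and a median of -0.14 at 12 h with 1 library per diet, and efferocytosis genes (10 of 12 positive, median 0.38, adjusted p = 0.00952, 5 members over the list alone). Fibro-adipogenic progenitor genes rose (10 of 12 positive, median 0.51, adjusted p = 0.00169), with Clec3b (1.27) and Dpt (0.70), and so did extracellular matrix genes (21 of 22 positive, median 0.45, adjusted p = 0.00223), none of them singly. With an estimated correlation the adjusted p was 0.519 for the cell cycle and for neutrophils, 0.555 for cytokines and for matrix, 0.444 for efferocytosis and 0.349 for progenitors. Pdgfra (0.33, adjusted p = 0.149) and Col1a1 (0.32, adjusted p = 0.748) did not pass. Other stromal lists were not called by camera. Their medians were 0.03 for endothelium (adjusted p = 0.766), -0.07 for smooth muscle and pericytes (0.923) and -0.11 for Schwann cells (0.896). They were -0.59 for tendon (0.467) and 0.16 for adipocytes (0.645). In the 18 h libraries alone the calls of neutrophils (0.40, adjusted p = 0.114), efferocytosis (0.33, adjusted p = 0.0996) and matrix (0.25, adjusted p = 0.114) ended, and without either 12 h library the medians were the same 0.40, 0.33 and 0.25. The matrix median was 0.28 without control 18 h replicate 1 and 0.72 without control 18 h replicate 2, the cell cycle median 0.75 without control 18 h replicate 1, and the cytokine call ended without PLX 18 h replicate 1 (0.12, adjusted p = 0.114) or control 18 h replicate 2 (0.23, adjusted p = 0.061), with a median of 0.62 without either 12 h library.

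Gene groups of metabolism and of fast fibres were lower after the PLX diet. All 31 oxidative phosphorylation genes had negative changes (median -0.64, adjusted p = 1.2e-11), of which 12 passed over all genes and 31 over the list alone, with Cox6a2 (-1.33) and Cox7a1 (-1.21) largest. Glycolysis genes fell (16 of 16 negative, median -0.94, adjusted p = 1.0e-08), with 10 past the threshold over all genes, among them Pgam2 (-1.67), hexokinase Hk2 (-1.62) and phosphorylase kinase Phkg1 (-1.48). Fast fibre genes fell (12 of 12 negative, median -1.11, adjusted p = 4.4e-06), with 8 past the threshold over all genes, including Pvalb (-1.62), Casq1 (-1.56) and the fast troponin Tnni2 (-1.38). With an estimated correlation the adjusted p was 0.114 for oxidative phosphorylation, 0.349 for glycolysis and 0.444 for fast fibres. Citric acid cycle genes (16 of 16 negative, median -0.59, adjusted p = 3.1e-06), fatty acid oxidation genes (20 of 21 negative, median -0.39, adjusted p = 0.000426) and atrophy genes (10 of 12 negative, median -0.55, adjusted p = 0.0064) fell too, with Idh3g (-0.76), Hadhb (-0.75) and Gadd45a (-1.47) as their largest called members. Their adjusted p was 0.444, 0.555 and 0.349 with an estimated correlation. The fatty acid oxidation median was -0.22 without control 18 h replicate 1. Myh4, the type IIB myosin, fell from 4212 ± 407 to 2090 ± 441 FPKM (-1.03, adjusted p = 0.0461), while Myh1 (-0.94, adjusted p = 0.431), Myh2 (-2.81, adjusted p = 0.181) and Dmd (-0.38, adjusted p = 0.39) did not pass. Slow fibre genes had a median of 0.31 and a mean of -0.15 (6 of 8 positive, adjusted p = 0.635), and a median of -1.01 at 12 h with 1 library per diet. The list of regenerating muscle, which holds Actc1, was not called either (6 of 10 positive, median 0.45, mean -0.05, adjusted p = 0.996). The 10 most abundant genes took 10.6% to 12.2% of all FPKM in the PLX libraries and 18.5% to 21.6% in the controls.

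**Figure D2:**
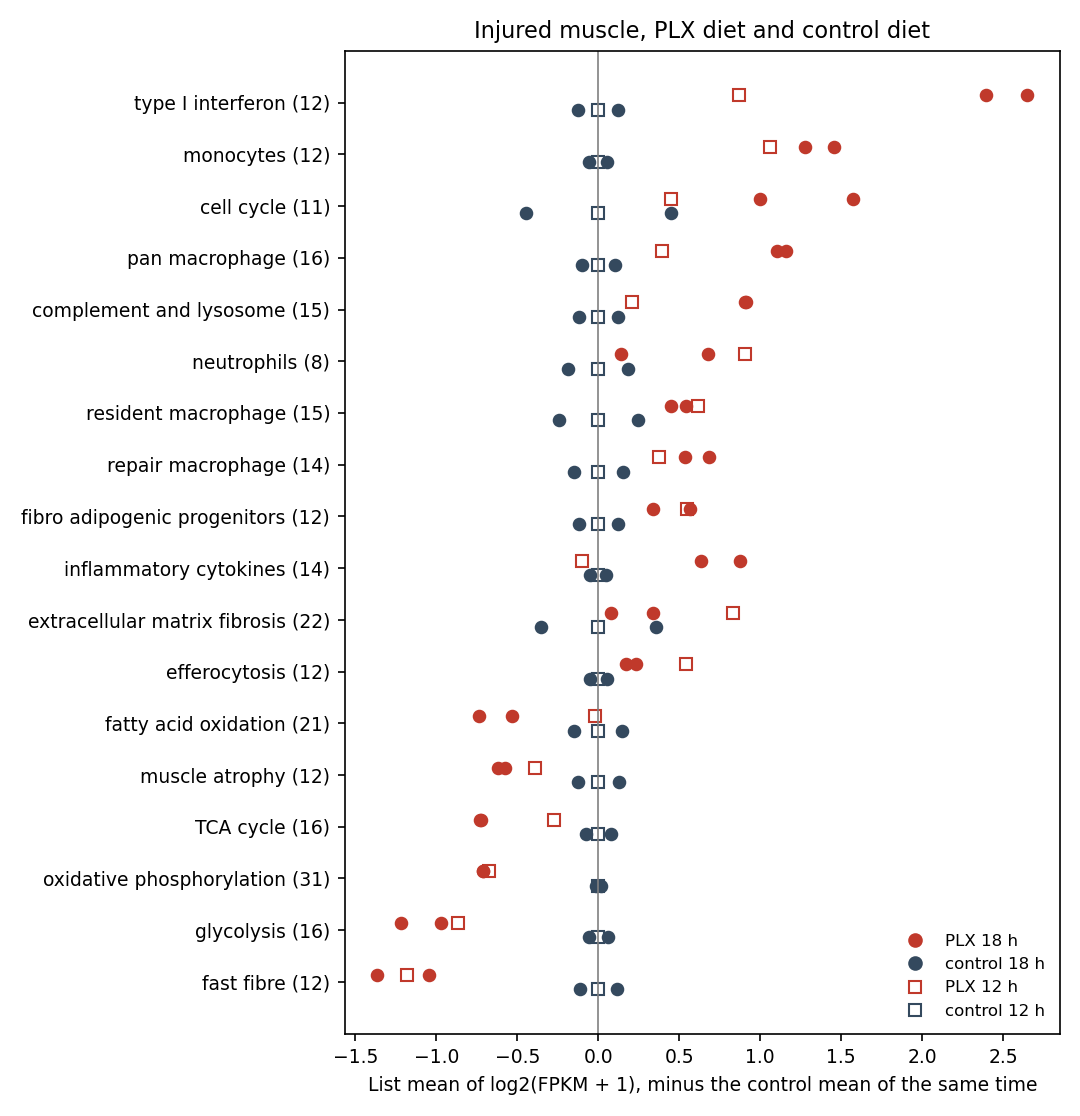
List levels in injured muscle. Each point is 1 library, the x axis is the mean log2(FPKM + 1) of a list's tested genes minus the control mean of the same time, red marks the earlier PLX diet, dark blue the control diet, circles 18 h and open squares 12 h; PLX libraries lie above the controls of their time for interferon, monocyte and macrophage lists and below them for oxidative phosphorylation, glycolysis and fast fibre lists.

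The balance of directions depended on scaling. Rescaling each library to the same total (TPM) moved the median change of all genes from -0.02 to 0.31 and the calls to 2196 higher and 266 lower, so directions in injured muscle are relative to the median gene, and the fatty acid oxidation median of -0.03 under TPM lies below that median gene. The number of calls rested on few libraries, with 0 genes without PLX 18 h replicate 1 (2636 with an unadjusted p under 0.05), 6 and 8 without control 18 h replicates 1 and 2, 180 without PLX 18 h replicate 2, 2243 without the PLX 12 h library and 2246 without the control 12 h library. Of 31 lists tested, 12 were higher and 6 lower, none with an estimated correlation and 9 by the directional fry test.

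Between 12 h and 18 h after injury, 1 gene was higher and 8 lower at 18 h with diet as a term, among 11578 tested (2279 with an unadjusted p under 0.05). Both 12 h libraries carry the title prefix 180B, while replicate 2 of each diet at 18 h carries 178B. The contrast of times is therefore in part a contrast of prefixes, which the labels do not explain. The immediate early transcription factor Egr1 fell (log2 change -2.06, adjusted p = 0.0286), from 457 and 318 FPKM in the control and PLX libraries at 12 h to between 59.7 and 121 FPKM in the 4 libraries at 18 h. The small GTPase Rrad (-2.08), tissue factor F3 (-1.67), the histone demethylase Kdm6b (-1.60), the cytokine Il6 (-1.56), the chemokine Ccl24 (-1.38) and Daam1 (-1.29) fell as well, and the small nucleolar RNA Snord16a, with 131 and 117 FPKM at 12 h, was at the floor of 0.01 FPKM in all 4 libraries at 18 h. The increase was the globin Hbb-bs, at the floor in both 12 h libraries and between 15.3 and 25.9 FPKM at 18 h, while its near-identical neighbour Hbb-bt had a change of 0.76 (adjusted p = 0.603), so reads of this family are not assigned to 1 gene with certainty. Cell cycle genes rose with time (11 of 11 positive, median 1.42, adjusted p = 3.4e-07, 10 members over the list alone), and so did resident macrophage genes (12 of 15 positive, median 0.66, adjusted p = 0.000247). Smooth muscle and pericyte genes (8 of 8 negative, median -1.17, adjusted p = 2.7e-05), endothelial genes (10 of 10 negative, median -0.59, adjusted p = 7.8e-06), neutrophil genes (8 of 8 negative, median -0.72, adjusted p = 0.000469) and inflammatory cytokines (9 of 14 negative, median -0.74, adjusted p = 0.00179) fell with time. With an estimated correlation the adjusted p was 0.418 for cytokines and 0.392 for the other 5 of these lists. Of 31 lists, 6 were higher and 12 lower, and none with an estimated correlation. With 1 library per diet at 12 h, 1001 genes were higher and 900 lower without the control 12 h library, 28 and 23 without control 18 h replicate 1, and 1 and 1 without any 1 of the other 18 h libraries.

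The test of whether the effect of the diet differed between 12 h and 18 h called 5 genes with a positive and 2 with a negative difference, taken as the effect at 18 h minus that at 12 h (2701 with an unadjusted p under 0.05). Of these 7 genes 6 were small RNA genes, which made up 0.302% of the genes tested. The other gene was the nonclassical class I gene H2-Q7 (3.24, adjusted p = 0.0469), named after its values were seen, with 17.9 and 16.4 FPKM after PLX against 1.63 and 1.22 in controls at 18 h, and 4.14 against 5.47 at 12 h. H2-Q7 lies on chromosome 17 from 35439155 to 35443773 in a family of near-identical genes, so its reads are not separated from theirs with certainty. With small RNA genes left out, a setting chosen after seeing the data, H2-Q7 did not pass.

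The resident macrophage gates with surface MHCII differed from those without it in dendritic and B cell transcripts and in the chemokine Ccl22. The values do not show which cells in these gates carried the transcripts. With 1 library per gate, and so no replicates, the gates are described by size, and a gene was called higher where both MHCII+ libraries lay at least 2-fold above both MHCII- libraries on FPKM + 1. By this rule 58 genes were higher and 5 lower among 11872. The chemokine Ccl22 had 12.2 and 21.9 FPKM in the GFP- and GFP+ libraries with MHCII and 0.312 and 0.417 in those without. The migratory dendritic cell receptor Ccr7 had 17.2 and 29.0 against 1.34 and 1.04 FPKM, the retinoic acid synthesis enzyme Aldh1a2 had 10.6 and 8.46 against 2.13 and 1.36 FPKM, and the B cell receptor component Cd79a had 14.2 and 13.5 against 0.443 and 1.28 FPKM. Mucl1 (mean log2 difference 4.38), Ly6d (2.75), Ear2 (3.10) and Plbd1 (2.64) were the other protein-coding genes among the increases with the largest gaps. Vsig4, a complement receptor of tissue macrophages, was lower, at 11.1 and 14.2 against 67.8 and 85.4 FPKM, as was the scavenger receptor Colec12 (-1.47). Amd2 (4.24) and Amd1 (-5.15) are near-identical genes that moved in opposite directions, so their reads are not told apart with certainty, and the small RNA genes Snora16a (15.9 and 62.0 FPKM in the MHCII+ gates), Snora52 (39.3 and 16.5 in the MHCII- gates) and Mir703 (52.4 and 59.7 in the MHCII- gates) were at the floor of 0.01 FPKM in the other 2 gates.

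By lists, the MHCII+ gates had higher dendritic cell genes (median log2 difference 0.84, above all 10000 random lists of like expression, with Ccr7 and Flt3 under the rule), and monocyte genes (0.67, with Ccr2 under the rule), each at percentile 100. Inflammatory cytokines (0.71) and repair macrophage genes (0.45) were at percentile 100 too, but the MHCII+ gates did not both lie above the MHCII- gates: list means of cytokines were 6.53 in MHCII+ GFP- and 7.02 in MHCII- GFP+, and those of repair genes 6.86 in MHCII+ GFP+ and 7.34 in MHCII- GFP-. B cell genes (2.08, 6 of 6 under the rule) and mast cell genes (1.79, with Tpsb2 under the rule), markers of cell types that a gate on CD11B, F4/80 and MERTK selects against, were at percentile 100 too. High percentiles were not particular to these lists. Type I interferon (0.39, percentile 100), neutrophil (0.33, 99.99), matrix (0.25, 99.97), red cell (0.60, 99.97) and fast fibre genes (0.30, 99.95) had them without any member under the rule. The median of the resident macrophage list was -0.17, at percentile 0.02, but its list mean was 8.44 in MHCII+ GFP- and 8.42 in MHCII- GFP+. The class II genes check the sort: H2-Aa had 3066 and 3941 FPKM in the MHCII+ libraries and 118 and 73.6 in the others, and all 10 class II genes met the rule.

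In the 2 gates with GFP from the Cx3cr1 locus, alarmin transcripts that also mark neutrophils were higher than in both gates without it, with 1 library per gate. The repair macrophage genes Gpnmb and Spp1 were lower. By the same rule 26 genes were higher and 12 lower in the GFP+ gates. The alarmins S100a9 and S100a8 had mean log2 differences of 1.95 and 1.55, and S100a9 reached 143 and 192 FPKM in the GFP+ libraries against 49.0 and 36.2 in the others. Both stand in the neutrophil list, and the LY6G- gate selects against neutrophils. These values therefore do not show which cells carried the transcripts. The growth factor Areg had 30.9 and 37.2 against 8.16 and 6.33 FPKM, and Lilra5 (2.68), Col14a1 (2.29), Gpr84 (1.86), Skil (1.78), Il21r (1.40) and BC002163 (2.95) were among the other increases with the largest gaps. The lysosomal glycoprotein Gpnmb was lower, at 35.8 and 3.52 FPKM with GFP against 160 and 181 without, as were osteopontin Spp1 (-1.94), Apoc1 (-2.60), Atp6v0d2 (-1.56), Acp5 (-1.53) and Syngr1 (-1.46). The microRNA gene Mir8104 had 81.4 and 55.8 FPKM in the GFP+ libraries and was at the floor of 0.01 FPKM in the others. Inflammatory cytokines had a median difference of 1.24, with Il1b (2.05) and Il1a (1.71) largest and none under the rule, and neutrophil genes one of 0.94, with 4 of 10 under the rule, both at percentile 100. Repair macrophage genes had a median of -0.73 with 3 of 14 under the rule, and the markers of red cells (-1.16), matrix (-0.48), smooth muscle (-0.55) and endothelium (-0.40, 10 of 10 negative) were lower in the GFP+ gates, all at percentile 0. Schwann cell (-0.45, percentile 0.01) and progenitor genes (-0.33, percentile 0.11) were lower too. Among the red cell markers Hba-a2 (-4.60) and its near-identical neighbour Hba-a1 (0.35) went opposite ways, with 0.06 and 59.2 FPKM in MHCII- GFP+, so their reads are not told apart with certainty. Cx3cr1 checks the sort, with 24.7 and 32.2 FPKM in the GFP+ libraries against 7.31 and 5.12.

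**Figure D3:**
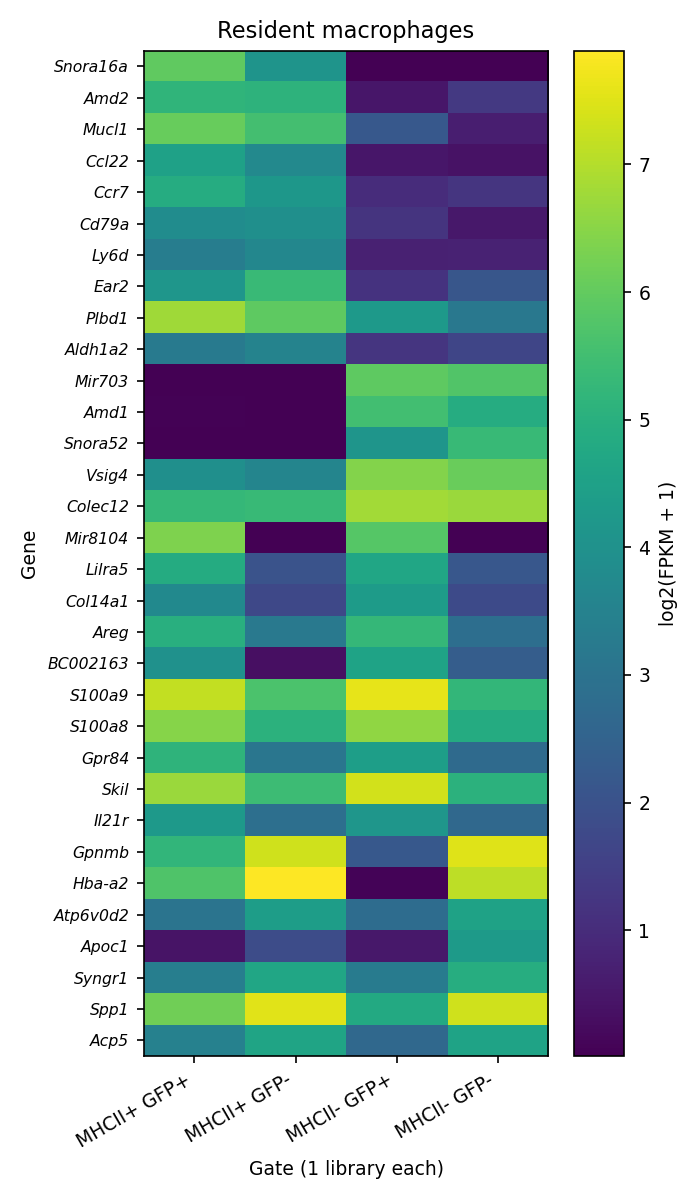
Genes that separated the resident macrophage gates. Colour is log2(FPKM + 1) for each named gene (y axis) in the 4 gates (x axis, 1 library each); Ccl22 and Ccr7 are high in both MHCII+ gates, Vsig4 in both MHCII- gates, S100a9 in both GFP+ gates and Gpnmb in both GFP- gates.

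Infiltrating cells changed from day 2 to day 6 after injury, from monocyte transcripts toward class II and dendritic ones. The titles carry 200k on day 2, 50k and 60k on day 4 and 15k on day 6, which the labels do not explain, so whatever these denote goes with day. Genes were called where day 6 differed at least 2-fold from day 2 with both day 4 libraries between or equal, with no test, and 325 genes were higher and 142 lower among 9805. Ly6c2 fell from 1563 FPKM on day 2 to 227 ± 21.2 on day 4 (SD, n = 2) and 130 on day 6, and the chitinase-like protein Chil3 from 353 through 27.9 ± 7.00 to 10.9 FPKM. The 10 class II genes all met the rule upward (median log2 difference 2.02), with H2-Aa largest (3.25). Monocyte genes had a median of -2.26, below all random lists, but only 3 of 12 met the rule downward and 1 met it upward. Dendritic cell genes had a median of 1.54, with Ccr7 (2.76) and Itgax (2.40) largest. Type I interferon genes (-0.90, with Oas1a and Irf7 under the rule) were lower on day 6. Inflammatory cytokines (-0.62, percentile 0.25) were lower too, led by Ccl2 (-3.01) and Ccl7 (-2.75), with none under the rule. Resident macrophage genes (1.02, 6 of 16 under the rule) were higher, with the scavenger receptors Cd163 (2.51) and Lyve1 (1.96) under the rule.

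The largest single increases from day 2 to day 6 among infiltrating cells were the imprinted RNA H19 (5.24), the immune checkpoint receptor Lag3 (4.24), the prostaglandin dehydrogenase Hpgd (3.86), Gpr34 (3.83), Tmem176b (3.69) and Ccl22 (3.62), and the muscle genes Acta1 (4.04), Mylpf (4.03), Myl1 (3.75) and Tnnc2 (3.72). The largest decreases besides Chil3 and Ly6c2 were Cd177 (-3.61), Rhov (-2.81), Cd300lf (-2.75), Pdpn (-2.75), thrombospondin Thbs1 (-2.67), Adam8 (-2.65), Dusp4 (-2.44) and Nt5dc2 (-2.31). Markers of other cells moved with time in the same libraries, with medians of 2.49 for fast fibre genes, 1.24 for matrix genes, 1.90 for T cell genes and 1.21 for natural killer cell genes, all at percentile 100. Leaving out a day 4 library gave 371 higher and 157 lower without replicate 1, and 478 and 301 without replicate 2.

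**Figure D4:**
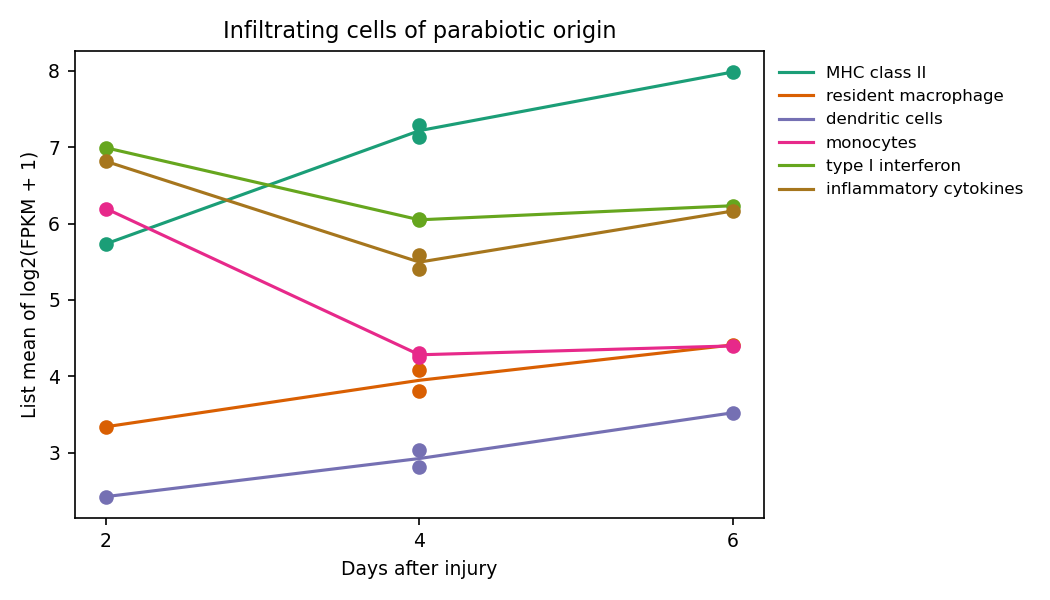
List levels in infiltrating cells by day. Points are libraries (1 at day 2, 2 at day 4, 1 at day 6), lines join the means, the x axis is days after injury and the y axis the mean log2(FPKM + 1) of the list; class II, dendritic and resident macrophage genes are higher on day 6 than on day 2, and monocyte, interferon and cytokine genes are lower.

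Resident and infiltrating cells were set side by side as levels only, because their tables were normalised separately and differ in sex, injury and gate. The median log2(FPKM + 1) of 18 resident macrophage genes was between 8.34 and 8.77 in the 4 resident gates and between 3.74 and 4.69 in the 4 infiltrating libraries. Monocyte genes had medians between 1.74 and 2.49 in the resident gates, and 6.12 on day 2 and 3.65 on day 6 in infiltrating cells. Pan-macrophage genes had medians between 9.12 and 9.76 in the resident gates and between 8.88 and 9.68 in the infiltrating libraries.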

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

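All tests of explanations in this part were chosen after the result was seen, while the tests of genes and lists were planned.

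A test of the difference itself called 5 genes with a positive and 2 with a negative difference, taken as the diet effect at 18 h minus that at 12 h after injury. Positive were the small RNA genes Snord35b (log2 difference 7.59), Mir682 (6.21), Snora15 (4.18) and Snora65 (4.02) beside H2-Q7, and negative were Snora75 (-4.25) and Snora28 (-3.87). Each of these 6 small RNA genes was above 0.01 FPKM in 1 library alone, a lone 12 h library: Snord35b had 193.8 and Mir682 73.7 FPKM in the control, and Snora75 had 18.2 FPKM after PLX. All 4 libraries at 18 h were at the floor for these 6 genes, so the differences come from 12 h alone, and their sizes rest on the floor and on the pseudocount. With 1 library per diet at 12 h, the spread within groups came from the 18 h libraries alone, where these 6 genes had none. Each of the 6 calls therefore rests on 1 value without a replicate. Small RNA genes made up 85.7% of the called genes and 0.302% of the tested genes. Genes shorter than the library fragments may add to this, which the values cannot separate. The share of small RNA genes does not bear on H2-Q7, which had a difference of 3.24 and lost its call when small RNA genes were left out. No biological explanation of these 6 genes was tested.

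Several changes went in opposite directions in the 2 whole-muscle experiments, with every library on the stated side of its controls, and the differences were not tested. Oxidative phosphorylation genes had a median log2 change of 0.27 in mdx muscle and -0.64 in injured muscle, and resident macrophage genes had -0.86 and 0.80. The macrophage gene F13a1 changed by -1.19 and 1.21, and Mid1ip1 by 1.21 and -0.99. The experiments differ in sex, disease, age, length of diet and the 3 days of regular food before injury, and these differences stay open. Of 9786 genes tested in both, 3 were called in both where 1.59 were expected, namely F13a1 and Mid1ip1 in opposite directions and Mss51 lower in both (-1.70 and -1.28), and the log2 changes had a correlation of -0.0869 across genes. Fast fibre genes were lower and progenitor and matrix genes higher in both experiments by camera with its preset correlation. Their adjusted p was 0.673, 0.673 and 0.771 in mdx muscle and 0.444, 0.349 and 0.555 in injured muscle with an estimated correlation, and the matrix call in injured muscle ended in the 18 h libraries alone (0.25).

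Interferon, monocyte and macrophage lists were higher and metabolic and fast fibre lists lower in injured muscle after the PLX diet by camera with its preset correlation, and none with an estimated correlation (lowest adjusted p 0.114). A smaller share of fibre RNA would raise the markers of every other cell type alike. The 48 genes of other non-fibre cells had a median log2 change of 0.05 in the values as deposited. The progenitor list among them had 0.51. Rescaling to TPM moved the median of all genes from -0.02 to 0.31, so the 0.05 alone cannot exclude a common rise. The 40 genes of the macrophage, monocyte and interferon lists had a median of 1.10 as deposited. The gap was 1.05, with every PLX library above the controls of its time. These lists were chosen after their rise was seen, so the gap is partly built in. Class II (0.10), dendritic cell (0.19) and mast cell genes (0.12) were left out of it. Rescaling by median-of-ratios, which does not use a total, gave an oxidative phosphorylation median of -0.62, with every PLX library below its controls. For these genes, relative to the median gene, this argues against normalisation to a total held by a few muscle genes as the whole cause. After rescaling to TPM the median was -0.28, but the same muscle genes weigh on that total, so TPM cannot decide this. Whether a smaller share of fibre RNA lowered the muscle genes cannot be told apart from regulation, because slow fibre genes, which it would lower too, had a median of 0.31 ranged from -0.26 to 0.56 with 1 library left out, and had -1.01 at 12 h. An effect of the diet on immune cells stays open for the immune part and was not tested further. As for chance, 1 of the 10 splits of the 6 injured libraries, the real one, gave as many called genes (1349, highest other 6), and 10 splits are too few for a share under 0.05. Some splits, among them that with 6 calls, put both 12 h libraries on the same side, which leaves less power with time as a term.

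Macrophage transcripts were lower in PLX-fed mdx muscle. One control rich in macrophage transcripts may account for the pan-macrophage part, since without control replicate 2 the median was -0.12 against -0.84 with it. The same control is argued against as the whole cause for the resident macrophage genes, with a median of -0.64 without it (adjusted p = 0.00888, and from 1.35e-05 to 0.00888 over the 6 libraries left out in turn; 0.19 with mean FPKM of at least 5 and 0.673 with an estimated correlation). A larger share of fibre RNA diluting all other cells is argued against, since 45 genes of other non-fibre cells had a median of 0.27 where macrophage genes had -0.84. The macrophage value pools both lists and includes control replicate 2, and the contrast was not repeated without that library. The 45 genes include the progenitor list (0.77), while smooth muscle and tendon genes each had 0.11 and Schwann cell genes -0.01. Loss of resident macrophages under CSF1R inhibition and lower expression per cell both stay open. For the count of called genes, 1 of the 10 splits of the mdx libraries, the real one, gave as many (16, highest other 3), and 10 splits are too few for a share under 0.05.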

How the results depend on the processing

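The setting with small RNA genes left out was chosen after seeing the data, and the other alternatives were planned.

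In mdx muscle limma-trend called 13 genes higher and 3 lower. With no filter on low values 0 were higher and 0 lower (2139 with an unadjusted p under 0.05, against 1648), and more genes were tested there. With mean FPKM of at least 5, 1 was lower. Rescaling to TPM gave 26 higher, reporter genotype as covariate gave 7 higher and 1 lower, and small RNA genes left out gave 23 higher. The cause was not tested. Leaving out 1 library gave 0 to 91 higher and 0 to 29 lower: 0 called without control replicate 1, control replicate 2, PLX replicate 2 or PLX replicate 3 (1250, 1505, 1175 and 1100 with an unadjusted p under 0.05), 5 without PLX replicate 1 and 120 without control replicate 3, of which 15 were among the 16. Of 306 values of named genes under alternatives, 187 kept direction and side of the threshold, 110 lost the call and 9 moved.

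In injured muscle 628 genes were higher and 721 lower. With no filter on low values 123 were higher and 177 lower, rescaled to TPM 2196 and 266, in the 18 h libraries alone 1227 and 1099, and with 4 cell means 1157 higher at 18 h. Leaving out 1 library gave 0 to 1181 higher and 0 to 1066 lower, with 0 in total without PLX 18 h replicate 1 (2636 with an unadjusted p under 0.05), 6 and 8 without control 18 h replicates 1 and 2, 180 without PLX 18 h replicate 2, and 2243 and 2246 without the PLX and the control 12 h library. Where 1 library was left in an arm, it was assumed to vary like the other groups. Named genes kept direction and side in 925 values, lost the call in 453, gained it in 6 and moved in 5.

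For time after injury (1 higher, 8 lower), no filter on low values gave 1 lower, mean FPKM of at least 5 gave 3 higher and 23 lower, and rescaled to TPM 4 were higher. Leaving out 1 library gave 1 to 1001 higher and 1 to 900 lower, the highest without the control 12 h library. For the difference between times (5 higher, 2 lower), pseudocount 0.1 gave 0 higher and 0 lower, no filter on low values 5 lower, mean FPKM of at least 5 gave 2 higher and 0 lower, rescaled to TPM 14 lower, no variance trend 4 lower, and small RNA genes left out 0 higher and 0 lower, all by limma-trend (2701 with an unadjusted p under 0.05 in the reported fit). Leaving out 1 library gave 1 to 7 higher and 0 to 3 lower. The cause was not tested, except that small RNA genes are the calls left out in the last setting.

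The title prefixes are not explained in the labels and the samples share only a prefix. Deviations of mdx libraries of the same prefix had correlations of 0.0593, 0.355 and 0.287, and every library correlated best with that of its own prefix. At 18 h the 2 injured pairs had 0.275 and the mismatched pairs -0.275. With 2 libraries per diet the deviations are mirror images, so these are 1 value and not separate ones. With title prefix as replicate block the mdx fit gave 14 higher and 1 lower (7 of these 15 among the 16). The injury fit gave 204 higher and 258 lower (455 of these 462 among the 1349). The time contrast gave 2 higher and 1 lower, and the difference between times 2 higher and 0 lower.

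Of the lists, camera called 9 higher and 4 lower in mdx muscle and 12 and 6 in injured muscle. With an estimated correlation camera called 0 higher and 0 lower in mdx muscle (adjusted p 0.673 to 0.987) and 0 and 0 in injured muscle (0.114 to 0.997). Directional fry gave 0 higher and 0 lower in mdx muscle and 4 higher in injured muscle, and fry mixed called 3 in mdx muscle in place of 13. Leaving out 1 library gave 6 to 11 higher and 4 to 7 lower in mdx muscle, and 10 to 12 and 6 to 7 in injured muscle. Without control replicate 2 the mdx medians of erythroid genes (-0.73, adjusted p = 0.02, against 0.27) and of complement and lysosome genes (0.13, adjusted p = 0.0193, against -0.06) reversed; with 1 library left out these medians ranged from -0.73 to 1.08 and from -0.10 to 0.13. List values kept direction and side in 375 cases in mdx muscle (45 lost the call, 20 gained it, 28 moved) and in 407 in injured muscle (39, 7 and 41).

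For the sorted cells, MHCII (58 higher, 5 lower) gave 88 and 17 with pseudocount 0.1, 21 higher with the 4-fold rule, 32 higher with mean FPKM of at least 5, and 169 and 80 with limma-trend on few degrees of freedom. GFP (26 higher, 12 lower) gave 43 and 25, 2 and 1 with the 4-fold rule, 7 lower with mean FPKM of at least 5, and 162 and 156 with limma-trend. Infiltrating cells (325 higher, 142 lower) gave 82 and 22 with the 4-fold rule, 158 higher with mean FPKM of at least 5, and 0 and 0 with limma-trend on day (965 with an unadjusted p under 0.05). Leaving out a day 4 library gave 371 to 478 higher and 157 to 301 lower. The progenitor list of infiltrating cells reversed with mean FPKM of at least 5 (-0.31 against 1.33), where fewer genes were left. Lists of resident cells moved in 1 of 232 cases, and named genes in 20 of 214. No paired analysis was possible for the sorted cells because their groups share fewer than 2 replicate numbers. Depth of the 3 tables without alignments is known only as a ratio, so the counting error of their low values is not given.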

Other observations

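The test of oxidative fibre genes was written before its result was seen, and the test of Pdgfra was chosen after.

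If the fibre transcripts of PLX-fed mdx muscle shifted toward oxidative types, further oxidative fibre genes outside the lists would be higher too. The 8 genes written down for this had a median log2 change of 0.94 and all 8 were positive: Csrp3 (1.93), Ankrd2 (1.76), Myoz2 (1.27), Cryab (1.12), Ldhb (0.75), myoglobin Mb (0.69), Ckmt2 (0.52) and Idh2 (0.30). The median was at percentile 100 among random lists of like expression. Random lists draw genes independently, while members of related lists vary together (estimated correlation 0.264 for slow fibres and 0.868 for oxidative phosphorylation). The percentile therefore overstates the evidence. No single gene passed over all genes, and the lowest PLX library mean (8.023) was close to the highest control mean (8.016). The prediction was met, but in the same libraries whose fibre and metabolism lists had prompted it, so it is no independent support. Such a shift stays open, and fibre types were not counted.

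Pdgfra averaged 1.11 ± 0.302 FPKM in the 3 mdx libraries that carry the Pdgfra reporter and 3.00 ± 1.05 in the other 3 (SD, n = 3 each), a 2.70-fold difference. An allele that replaces 1 copy of the gene could lower it, but the exact permutation p was 0.1, the smallest that 3 against 3 can give. The median of the other 11 progenitor genes was higher in the libraries without the reporter by 0.56 on the log2 scale, which was not tested, so an effect of the allele cannot be told apart from a lower share of progenitor RNA. The reporter was carried by 1 PLX and 2 control libraries.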
